A study of Homo sapiens with 4 samples.

How the data were processed

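PolyA RNA was sequenced from 4 samples of A549, an established human lung carcinoma cell line, carrying an A-FOS gene that doxycycline switches on. The sample titles call it a knock-in, and the series' design text says that the insertion by piggyBac was random. The labels put 2 libraries in a group without doxycycline (minus Dox) and 2 in a group with 1 µg/mL doxycycline (plus Dox), and do not say whether the 2 libraries of a group came from separate cultures. All p-values therefore measure only the spread between these samples, which may be technical. Per the labels' protocols, RNA was treated with DNase I and the libraries were made with a stranded mRNA kit and sequenced as paired ends.

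The deposited files hold raw counts per Ensembl gene, 1 file per library, with no normalization, per the file headers and the values. Tools named per the submitters' processing notes, with no role or order given, are DRAGEN, cutadapt 4.0, STAR 2.7.10b, featureCounts 2.0.3 and DESeq2 2.11.40.7, and the build named there is hg38. The annotation release and the strand setting of the counting are not given in the sources used here. Without them, reads of a gene and of an overlapping or antisense gene cannot be told apart, and reads of near-identical genes may have been split or dropped. Among the 122 named genes, 6 shared over 25% of their exon bases with another gene in GENCODE 29, and these are given as uncertain. Each file lists 58051 genes, of which 57447 were found in GENCODE 29, 56948 in a table of gene symbols and 41445 have a symbol. The 13 mitochondrially encoded mRNAs are listed at 0 in every library, so no share of mitochondrial RNA could be used as a sign of RNA quality.

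Everything below was computed from these counts in R 4.3.3. Genes were kept with edgeR's filterByExpr at its defaults, which left 18046 genes, and libraries were scaled by TMM (factors 0.930 and 0.926 for minus Dox, 1.077 and 1.079 for plus Dox). The test was edgeR 4.0.16's quasi-likelihood test of group, with no other term, and Benjamini-Hochberg adjustment over all tested genes at an adjusted p threshold of 0.05. Levels are TMM-scaled CPM (counts relative to the scaled library size), and fold changes are the fitted plus Dox over minus Dox values on the log2 scale. Values of n = 2 carry an SD over both libraries of a group. The 23 gene lists, with 472 names of which 471 were matched to a gene (SOD2 was not), were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation between genes 0.01), with Benjamini-Hochberg adjustment over the 22 lists that had at least 3 tested members. Camera was repeated with the correlation estimated from the data, and fry was run for directional and mixed change. Calls lost with an estimated correlation do not by themselves show strong correlation between genes. For AP-1 targets the estimate was 0.012, near the preset 0.01, and camera's unadjusted p still went from 2.10e-09 to 0.0275. With an estimate, camera also takes its degrees of freedom from the 4 libraries, which leave few. Camera compares a list with the other genes, and fry does not.

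Genes named in the text were chosen by a rule set before the data were examined, as were the gene lists, the tests and the alternatives. The rule took the 12 largest rises and the 12 largest falls by fitted fold change among genes past the threshold, with a symbol, at least 5 CPM on average in the group where they were higher, and both plus Dox libraries on the same side of both minus Dox libraries. It also took every tested member of the AP-1 family list with FOXA1 and FOXA2, and from each other list up to 4 members with the lowest adjusted p. XIST and Y-linked genes were left out. Other genes were named after their values were seen, and this is said where they appear. Results of a few genes that the rule took are not reported here.

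The pipeline was tested on simulated data, with counts drawn from the real means and library sizes of this comparison over 17628 genes. At each fold 48 or 49 of these genes were changed, and 17434 were not changed. At this depth and group size it recovered 40.8% of genes changed 1.2-fold, 62.5% of those changed 1.5-fold, 87.5% of those changed 2-fold and 95.9% of those changed 4-fold. Of 17434 unchanged simulated genes 9 were called, which made up 6.08% of the calls. These shares hold where few genes change. The real comparison called 56.9% of tested genes, so recovery and false share may differ there. A simulated list moved as a whole passed with the preset correlation and with the estimated one (adjusted p = 0.0367 with an estimated correlation), and 0 of 20 unchanged lists passed. The simulated genes were drawn independently and only those of the moved list changed. False calls from correlated genes, or among many changed genes, were therefore not tested. Total counts ranged from 31104964 to 40526912, and a count of 0 in a library allows up to 3 counts, between 0.0740 and 0.0964 CPM before scaling, for counting error only.

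Alternatives were other scaling factors (RLE, upper quartile, library size only), other filters, thinning to the smallest total, a replicate block, each library left out in turn, mitochondrially encoded genes left out, DESeq2 1.42.0 and limma-voom. Removal of a trend of fold change on GC content, exon length and abundance was added after seeing the data, and list medians printed with it lie 0.019 above the centring used for single genes and list tests. The rule for leukocyte RNA is the last of several tried after seeing the data: a bound from counting error also went against it, while a t interval over 2 libraries per group and a permutation rule that could not decide left it open. Replicates of 1 group differed by more than sampling noise (chi-square per degree of freedom 3.90 in minus Dox and 2.21 in plus Dox), so neither pair was treated as repeat files of 1 library. This does not show separate cultures, since repeat libraries of 1 culture would differ as well, and the 4 libraries are separate samples per the labels. Libraries of A549 without A-FOS grown with doxycycline are not analysed here, and neither is any binding data for FOXA1 or AP-1.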

Results

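The data are polyA RNA-seq counts from A549 cells with a randomly integrated, doxycycline-inducible A-FOS, in 2 libraries without doxycycline (minus Dox) and 2 libraries with 1 µg/mL doxycycline (plus Dox). A-FOS is a dominant-negative form of FOS whose acidic extension replaces the DNA-binding basic region, so that it pairs with JUN proteins and keeps them from DNA. AP-1 is the family of FOS, JUN, ATF and MAF dimers that bind enhancers after growth and stress signals. Total counts were 36377784 and 40526912 in the minus Dox libraries and 32727539 and 31104964 in the plus Dox libraries. A count was present for 26187 and 26258 genes without doxycycline and for 26781 and 26828 genes with it. The 10 most abundant genes of each library held 6.03% and 6.13% of the counts in minus Dox and 4.23% and 4.18% in plus Dox. Across tested genes Pearson's r was 0.993 within each group and 0.964 to 0.966 between groups, where genes are not independent replicates.

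The series concerns how FOXA1 and AP-1 bind DNA together, and this comparison asks what gene expression does when A-FOS is induced. With doxycycline, reads counted to FOS rose 34.4-fold, while its partner JUN and its relatives FOSL1 and FOSL2 fell. Over 16 tested members of the AP-1 family 5 rose, 6 fell and 5, JUND and FOSB among them, did not pass. Of 25 tested genes listed as AP-1 targets 19 fell and 3 rose, and the list's call in a gene set test is lost with an estimated correlation (adjusted p = 0.257). The hyaluronan receptor CD44 went from 754 ± 6.97 to 184 ± 5.57 CPM and the urokinase gene PLAU from 152 ± 3.99 to 15.5 ± 0.843 CPM (SD, n = 2), though 31.1% of the exon bases of PLAU are shared with another gene. The keratin KRT7 and the matrix protein TGFBI fell from 4544 to 526 CPM and from 2959 to 463 CPM. FOXA1 itself had 42.6 ± 0.314 CPM without and 41.3 ± 0.0275 CPM with doxycycline (SD, n = 2).

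Of 18046 tested genes, 5133 were higher and 5132 lower in plus Dox by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, together 56.9% of tested genes. Most of these differences were small, with a median absolute log2 fold change of 0.51, and 1209 of the higher and 1084 of the lower genes also had a fitted change of at least 2-fold. In 13892 genes (77.0%) the CPM of both plus Dox libraries lay on 1 side of both minus Dox libraries, against 33.3% by chance for 2 against 2. Among protein-coding genes 4691 rose and 4452 fell, and among lincRNAs, long non-coding RNAs between genes, 105 rose and 178 fell. The split into higher and lower depends on the scaling: 50.0% of called genes were higher with TMM and 72.9% with library size only, which moves the median of all tested genes from 0.00 to 0.22 on the log2 scale. Doxycycline and A-FOS induction go together in these libraries, so no comparison here separates them.

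**Figure D1:**
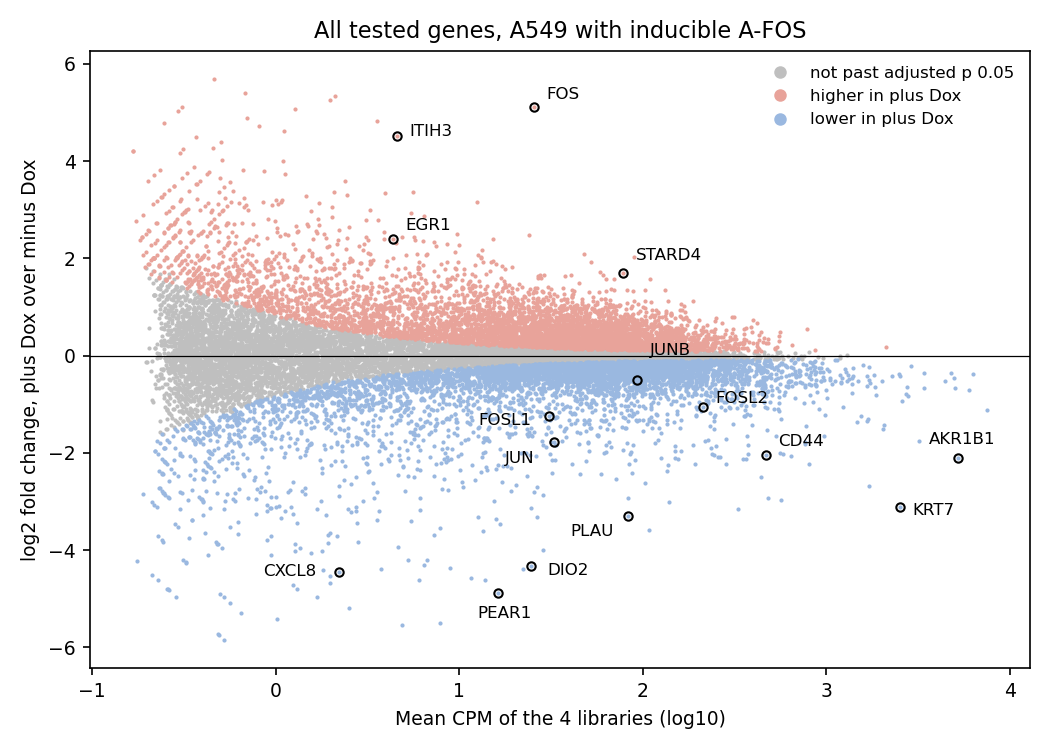
Each point is a tested gene, with its mean CPM over the 4 libraries on a log10 axis and its log2 fold change of plus Dox over minus Dox on the other axis. Genes at 0 in both libraries of a group are not drawn, circles mark 15 genes named in the text, and FOS lies at 5.10 while KRT7 lies at −3.11 and AKR1B1 at −2.11.

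FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230 in hg38) rose from 1.44 ± 0.113 to 49.8 ± 1.64 CPM (SD, n = 2), a log2 fold change of 5.10 (SE 0.11), with an adjusted p of 1.12e-29 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The counts are per gene and have no entry for A-FOS, so reads of the integrated gene and of the FOS locus are not separable in them. FOSL1 fell by 1.25 (43.7 to 18.4 CPM) and FOSL2 fell by 1.06 (287 to 138 CPM) on the log2 scale. FOSB did not pass, with 2.32 ± 0.108 and 2.00 ± 0.543 CPM (SD, n = 2). JUN (ENSG00000177606, chromosome 1, 58780788 to 58784327) fell from 51.2 ± 2.53 to 14.8 ± 0.825 CPM (SD, n = 2), a log2 fold change of −1.79 (SE 0.07) with an adjusted p of 3.48e-21 by the same edgeR test. JUNB fell by 0.51 and the stress-induced ATF3 fell by 0.90 on the log2 scale, and JUND had 103 ± 5.60 and 98.8 ± 6.03 CPM (SD, n = 2). The small MAF genes, which lack an activation domain, moved apart: MAFG rose by 0.45 and MAFF by 0.47, and MAFK had a log2 fold change of −0.12. ATF2 rose by 0.28 and BATF2, an interferon-inducible family member, by 0.76 on the log2 scale. BATF3, JDP2 and ATF7 did not pass, at −0.14, 0.14 and 0.00 on the log2 scale, and ATF7 shares exon bases with other genes (18.3% on the same and 27.1% on the opposite strand), which leaves its count uncertain.

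Over the AP-1 family 5 of 16 tested members rose, 6 fell and 5 did not pass, and the counts adjusted over the list alone were also 5 and 6. With library size only 8 rose and 5 fell (median 0.12), and in DESeq2 3 rose and 5 fell. As a list the family did not pass limma's camera test (adjusted p = 0.568), and its median of −0.09, its mean of 0.07 and the direction of the tests (down in camera, up in fry) differ in sign. FOS, among the 5 that rose, pulls the mean up, at 5.10 against 0.76 for the next highest member. Its reads may include those of A-FOS. The mixed fry test, which counts changes either way, gave an adjusted p of 1.14e-04. The weakest members did not pass in every setting: without plus Dox replicate 1 edgeR's adjusted p was 0.0659 for BATF2, 0.0743 for MAFF and 0.221 for MAFK. MAFK also missed without minus Dox replicate 2 (0.206) and plus Dox replicate 2 (0.127), while JUND passed without minus Dox replicate 1 (0.0118). DESeq2 on all 4 libraries gave adjusted p-values of 0.0916 for BATF2, 0.0646 for MAFF and 0.0852 for MAFK. With library size only JUND (0.15, edgeR adjusted p = 0.00905), ATF7 (0.21, 0.00342) and JDP2 (0.36, 9.20e-05) passed as higher, and MAFK (0.094) and BATF3 (0.077) did not pass. With the GC, length and abundance trend removed ATF2 passed as lower (−0.22, edgeR adjusted p = 0.00177) and JUND as higher (0.21, 6.84e-04), and MAFK did not pass (0.385).

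**Figure D2:**
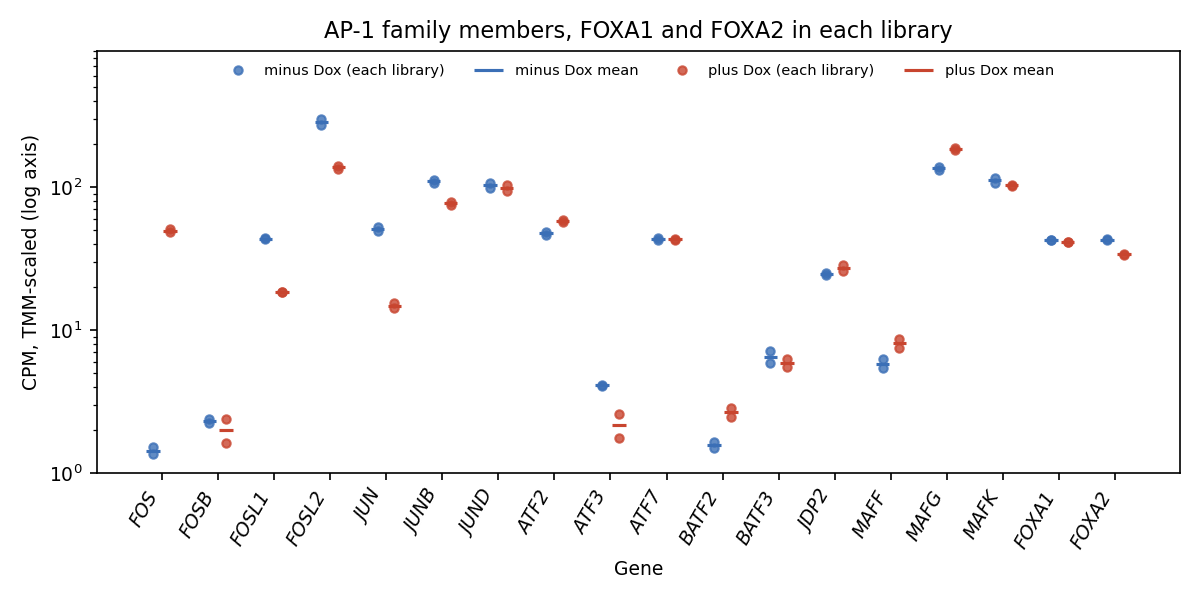
TMM-scaled CPM on a log axis of each AP-1 family member tested, FOXA1 and FOXA2, with 1 point per library and a bar at the mean of the 2 libraries of a group. FOS goes from 1.44 to 49.8 CPM and JUN from 51.2 to 14.8 CPM, and the points of FOXA1 lie at 42.6 and 41.3 CPM on average.

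FOXA1, the pioneer factor of the series (ENSG00000129514, chromosome 14, 37589984 to 37596059), had a log2 fold change of −0.05 (SE 0.06) and an adjusted p of 0.554 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With library size only it passed as higher, at 0.17 (edgeR adjusted p = 0.0191), where the median of all tested genes was 0.22, and it lay at 0.025 with the GC, length and abundance trend removed. Its relative FOXA2 fell from 43.0 to 33.9 CPM, a log2 fold change of −0.35, and did not pass with library size only (edgeR adjusted p = 0.0880). Among 18 tested FOXA and endoderm transcription factors 5 rose, 8 fell and 5 did not pass, with the same counts adjusted over the list alone, but 7 rose and 7 fell with library size only. SOX9, a regulator of lung progenitors, fell from 107 to 52.1 CPM, the hepatocyte factor HNF4A from 78.8 to 44.6 CPM, and the epithelial ETS factors ELF3 from 219 to 151 CPM and EHF from 62.2 to 34.7 CPM. GRHL1, an epithelial factor named after its value was seen, rose from 0.879 to 3.46 CPM. The list had a median of −0.06 (0.15 with library size only) and did not pass camera (adjusted p = 0.153). Directional fry, which has no other genes as reference, placed it lower (adjusted p = 0.0239).

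AP-1 targets had the lowest median of the lists in the main fit, −0.99 on the log2 scale. Of 25 tested members 19 were lower, 3 higher and 3 not past, with the same counts adjusted over the list alone. With the GC, length and abundance trend removed the NF-kB list lay slightly lower (−0.83 against −0.82). CD44 (chromosome 11, 35138870 to 35232402) had a log2 fold change of −2.04 (SE 0.04) and an adjusted p of 6.58e-32 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. PLAU fell by 3.29 on the log2 scale, though 31.1% of its exon bases are shared with a gene on the opposite strand. The chromatin protein HMGA1 fell from 880 to 479 CPM. Among members named after their values were seen, the neutrophil chemokine CXCL8 fell from 4.21 to 0.187 CPM, while the EGF-receptor ligand HBEGF rose from 6.69 to 13.1 CPM and the protease MMP10 by 1.07 on the log2 scale. Camera placed the list below the other genes (adjusted p = 4.62e-08). The call is lost with an adjusted p = 0.257 with an estimated correlation, though the estimate of 0.012 was near the preset 0.01.

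Inflammatory genes under NF-kB fell in 15 of 17 tested members, with 1 higher, 1 not past and the same counts adjusted over the list alone. Complement C3 fell from 352 to 139 CPM, TNFAIP2 from 407 to 194 CPM, and the chemokines CXCL5 from 237 to 120 CPM and CCL2 from 112 to 54.5 CPM. The member that rose was the adhesion molecule ICAM1, from 8.04 ± 0.844 to 27.5 ± 1.29 CPM (SD, n = 2), named after its value was seen. The median was −0.91 and the camera adjusted p 1.96e-06, against an adjusted p = 0.257 with an estimated correlation.

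Mesenchymal genes and cell adhesion genes fell on balance. In the mesenchymal list 14 of 19 tested members fell, 4 rose and 1 did not pass, also adjusted over the list alone. TGFBI (log2 fold change −2.68), the fibrillar collagen COL5A1 (468 to 99.5 CPM), the collagen cross-linking enzyme LOXL2 (371 to 99.0 CPM) and the receptor kinase AXL (437 to 133 CPM) had its lowest adjusted p-values in edgeR. The members that rose, named after their values were seen, were ZEB1, a repressor of epithelial genes, the collagens COL6A1 and COL6A2, and the cross-linking enzyme LOX, with log2 fold changes of 0.50, 0.57, 0.99 and 1.22. Of 18 integrins and laminins 14 fell, 3 rose and 1 did not pass (15 lower adjusted over the list alone). They include ITGB4 and LAMA3, which anchor epithelial cells to the basement membrane, from 167 to 71.9 CPM and from 86.4 to 31.1 CPM. The TGF-beta-activating integrin ITGB6 fell from 24.9 to 2.04 CPM and the laminin receptor ITGA3 from 709 to 394 CPM. YAP and TEAD targets fell in 15 of 20 members, with 3 higher and 2 not past, also adjusted over the list alone, and 11 fell and 5 rose with library size only. They include AXL, the growth factor TGFB2 (−1.52; 26.6% of its exon bases shared with another gene), the Hippo regulator WWC1 (299 to 149 CPM) and ANKRD1 (−1.60). Camera gave adjusted p-values of 7.42e-05, 6.78e-05 and 7.42e-05 for the mesenchymal list, the integrins and laminins, and the YAP and TEAD targets, with medians of −0.66, −0.58 and −0.40. All 3 calls are lost with adjusted p = 0.257, 0.276 and 0.257 with an estimated correlation. The median of integrins and laminins was −0.37 with library size only and −0.35 with the GC, length and abundance trend removed, and that of YAP and TEAD targets −0.18 and −0.23.

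Epithelial and airway genes also went down in part. KRT7 (log2 fold change −3.11, SE 0.03) and KRT19 (122 to 21.1 CPM), keratins of simple epithelium, fell, as did KRT8 (5280.1 to 3656 CPM). The pore-forming claudin CLDN2 fell from 113 to 52.1 CPM. KRT8 turned to 0.28 with the GC, length and abundance trend removed. Over the epithelial list 9 of 19 members fell, 3 rose and 7, the cadherin CDH1 among them at −0.14, did not pass, with the same counts adjusted over the list alone. Only 6 fell with library size only, with 3 higher, and with the trend removed, with 4 higher. Its median was −0.19 (0.025 with library size only) and its camera adjusted p 0.0164, against an adjusted p = 0.276 with an estimated correlation and 0.280 with the trend removed. In the alveolar and airway list 5 of 10 members fell, 2 rose and 3 did not pass, also adjusted over the list alone. Caveolin CAV1 fell from 588 to 164 CPM, the airway mucins MUC5AC from 9.69 to 1.70 CPM and MUC5B from 20.2 to 8.61 CPM, and the lamellar body transporter ABCA3 from 120 to 87.3 CPM. That list's median was −0.41 (−0.20 with library size only) and its camera adjusted p 0.0453, against 0.0650 with no filter on low counts and an adjusted p = 0.281 with an estimated correlation.

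NRF2 targets, the genes of antioxidant and NADPH metabolism, fell in 16 of 23 members, with 5 higher and 2 not past, also adjusted over the list alone, and 13 fell and 9 rose with the trend removed. The aldo-keto reductases AKR1B1, AKR1C1 and AKR1B10 fell from 8512 to 1974 CPM, from 939 to 230 CPM and from 2995 to 1121 CPM, though these genes have close paralogs between which the counting may have split reads. Heme oxygenase HMOX1, which degrades heme, fell from 395 to 96.4 CPM. Members that rose, named after their values were seen, include the glutathione synthesis genes GCLM (0.45) and GCLC (0.21) and the cystine transporter SLC7A11 (0.34). The median was −0.62 (−0.40 with library size only) and the camera adjusted p 1.59e-07, against an adjusted p = 0.257 with an estimated correlation. With the GC, length and abundance trend removed the median was −0.08 and the adjusted p 0.0516.

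Genes of DNA replication, cholesterol synthesis and respiration showed smaller falls. MCM7, MCM5 and MCM4, subunits of the replicative helicase, fell by 0.73, 0.72 and 0.61 on the log2 scale and the sliding clamp PCNA by 0.50 (0.028 with the GC, length and abundance trend removed). In that G1/S list 14 of 24 members fell, 4 rose and 6 did not pass, also adjusted over the list alone, but 12 fell and 10 rose with library size only, and 11 fell and 5 rose with the trend removed. Only 2 rose without minus Dox replicate 1, plus Dox replicate 1 or plus Dox replicate 2, with no filter and in DESeq2. Of 21 cholesterol genes 16 fell and 5 rose, also adjusted over the list alone, with 11 and 6 with library size only. The sterol carrier STARD4 rose from 37.0 to 120 CPM and the desaturase SC5D from 18.2 to 39.6 CPM, with the epoxidase SQLE down from 202 to 137 CPM and the sterol sensor INSIG1 down from 108 to 72.4 CPM. Nuclear genes of oxidative phosphorylation fell in 16 of 25 members, rose in 0 and did not pass in 9, also adjusted over the list alone, with UQCRC1, ATP5MC1, COX4I1 and CYC1 at −0.42, −0.45, −0.36 and −0.37. That balance depends on the scaling: 7 rose and 6 fell with library size only, and 9 rose and 6 fell with the trend removed. CYC1 lay at 0.011 with the trend removed. Medians were −0.33, −0.36 and −0.18, and camera adjusted p-values 0.00262, 0.0210 and 0.00148, for the G1/S, cholesterol and respiration lists, against adjusted p = 0.257, 0.276 and 0.276 with an estimated correlation. None of the 3 lists passed with library size only (0.0639, 0.0836 and 0.356, where the respiration median was 0.035) or with the trend removed (0.280, 0.0908 and 0.601). The G1/S and cholesterol medians were −0.11 and −0.15 with library size only, and −0.07 and −0.22 with the trend removed. The cholesterol list missed without any 1 of the 4 libraries (0.233 to 0.311) and with a replicate block (0.256), and the respiration list missed without plus Dox replicate 1 (0.108).

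The growth, stress and interferon lists did not pass camera, with members moving both ways. Of 18 MAPK feedback and immediate early genes 8 rose, 7 fell and 3 did not pass. MYC fell from 149 to 50.8 CPM and the receptor EPHA2 from 528 to 350 CPM. The early growth response gene EGR1 rose from 1.40 to 7.33 CPM and the ERK phosphatase DUSP6 from 6.12 to 14.7 CPM (40.5% of its exon bases lie opposite another gene). Of 20 interferon-stimulated genes 9 rose, 3 fell and 8 did not pass (9 and 4 adjusted over the list alone), against 12 and 1 with library size only (median 0.60) and 5 and 2 of 22 in DESeq2. The exonuclease ISG20 rose by 1.64 and IFIT1 by 0.51, with OAS1 and OAS3 at −0.49 and −0.26. OAS3 did not pass with library size only (edgeR adjusted p = 0.383) or with the trend removed (0.751). G2/M genes rose in 6, fell in 12 and did not pass in 6 of 24 members (6 and 13 adjusted over the list alone), but 13 rose and 3 fell with library size only, and 5 rose and 4 fell with the trend removed. CDC20, TPX2 and KIF20A, which act in mitosis, lay at −0.76, −0.45 and −0.58, and the kinase CDK1 rose by 0.66. Of 20 p53 targets 8 rose, 10 fell and 2 did not pass, but 11 rose and 7 fell with library size only, and 6 rose and 8 fell in DESeq2. DDB2, PHLDA3 and TP53I3 lay at −0.98, −0.84 and −0.65, and the ribonucleotide reductase subunit RRM2B rose by 0.85. Adjusted over the list alone the MAPK and p53 counts were the same. Camera's adjusted p was 0.924 for the MAPK list, 0.357 for the interferon and the G2/M lists and 0.507 for the p53 list, with medians of 0.03, 0.39, −0.10 and −0.05. Directional fry placed the interferon list higher (adjusted p = 0.00340) and the p53 list lower (0.00183). The MAPK and G2/M lists did not pass it (fry adjusted p = 0.930 and 0.0689).

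Stress and metabolic lists were split in the same way. Of 22 ATF4 genes 8 rose, 9 fell and 5 did not pass, but 10 rose and 6 fell with library size only, and 9 rose and 6 fell with the trend removed. The pseudokinase TRIB3 fell from 153 to 57.7 CPM and the mTOR inhibitor DDIT4 from 73.7 to 25.1 CPM (41.2% of its exon bases lie opposite another gene). The secreted STC2 fell from 22.0 to 6.62 CPM, and the amino acid transporter subunit SLC3A2 from 816 to 548 CPM. Of 16 genes of the unfolded protein response 4 rose, 9 fell and 3 did not pass (4 and 10 adjusted over the list alone), but 8 rose and 4 fell with library size only, and 7 rose and 1 fell with the trend removed. The co-chaperones DNAJB9 and DNAJC3 and the degradation adaptor SEL1L rose by 1.00, 0.55 and 0.48. The chaperone HSPA5 fell from 604 to 462 CPM, but not with the trend removed (−0.02, edgeR adjusted p = 0.672). Of 20 hypoxia and glycolysis genes 8 rose, 10 fell and 2 did not pass (9 and 10 adjusted over the list alone), but 11 rose and 8 fell with library size only, and 9 rose and 7 fell with the trend removed. PFKFB3, which drives glycolysis, fell from 644 to 306 CPM, the glycolytic enzyme ENO1 from 3593 to 2009.8 CPM and the glucose transporter SLC2A1 from 359 to 173 CPM. The prolyl hydroxylase P4HA1 rose from 43.4 to 85.1 CPM. The ATF4 counts were the same adjusted over the list alone. Directional fry placed the ATF4 and hypoxia lists lower (adjusted p = 0.00244 and 0.00403), and the unfolded protein response list did not pass it (0.930). Camera's adjusted p was 0.357 for each of these lists, with medians of −0.14, −0.14 and 0.01. The hypoxia list had a mean of −0.10 and a camera direction of down, and it passed without minus Dox replicate 1 (0.00213) or without minus Dox replicate 2 (0.00261).

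Of 15 leukocyte markers 6 were tested, 0 rose and 2 fell, CD14 from 2.23 to 1.08 CPM and the B-cell gene CD79A from 1.05 to 0.469 CPM. CD79A missed without minus Dox replicate 2 (edgeR adjusted p = 0.507) or plus Dox replicate 1 (0.187), with library size only (0.0604) and in DESeq2 (0.165). Of 11 tested fibroblast and endothelial markers 2 rose, 4 fell and 5 did not pass. THY1, a surface glycoprotein, rose from 26.1 to 43.3 CPM. Levels of VWF (0.0444 to 0.570 CPM), FAP (0.543 to 0.0426 CPM) and CDH5 (1.01 to 0.271 CPM) were low, with VWF in minus Dox and FAP in plus Dox near the counting floor. The size of the CDH5 change rested on single libraries, with a log2 fold change of −4.92 without plus Dox replicate 1 and −0.98 without plus Dox replicate 2. In DESeq2 on all 4 libraries CDH5 missed (adjusted p = 0.0621). Counts adjusted over the list alone were the same for both. Neither list passed camera (adjusted p = 0.753 and 0.924), and the fibroblast and endothelial list was down in camera and up in fry. Across the 22 tested lists 11 passed camera, all of them lower in plus Dox, 0 passed with an estimated correlation, 16 passed directional fry and 21 passed mixed fry.

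**Figure D3:**
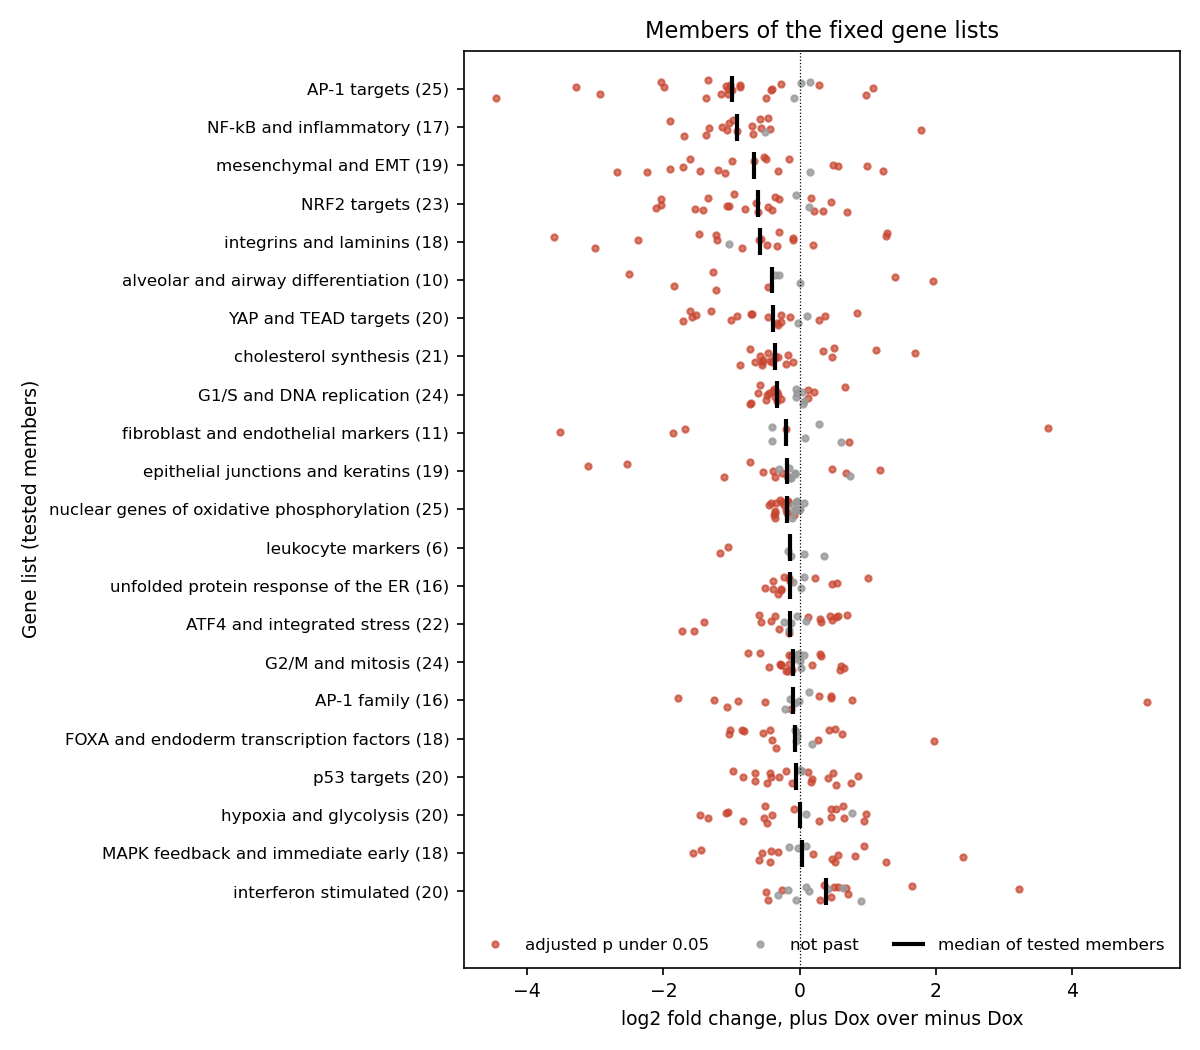
Log2 fold change of plus Dox over minus Dox for each tested member of the fixed gene lists, with 1 point per gene, colour by the edgeR adjusted p and a bar at the list median. Medians run from −0.99 for AP-1 targets to 0.39 for interferon-stimulated genes, and points of most lists lie on both sides of 0.

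The largest rises by the rule for named genes, after FOS, were ATP1B2, a sodium pump subunit, from 0.244 to 6.88 CPM, and ITIH3, a secreted hyaluronan-binding protein, from 0.378 to 8.75 CPM. Next came QPRT, an enzyme of NAD synthesis (3.37 on the log2 scale), the semaphorin SEMA3G (3.34), the troponin TNNC1 (3.16), the neurotrophin receptor NGFR (2.99; 27.1% of its exon bases lie opposite another gene) and the keratin KRT4 (2.94). KIRREL2, SYNE3, RASAL1 and the transporter ABCA8 followed at 2.87, 2.80, 2.78 and 2.55. SEMA3G, TNNC1 and ITIH3 lie close together on chromosome 3 (52433053 to 52809009), and whether their rises are separate was not tested. Among the largest falls were the carboxypeptidase CPA4 (15.4 to 0.337 CPM), the receptor PEAR1 (31.4 to 1.07 CPM) and the forkhead factor FOXQ1 (11.6 to 0.465 CPM). CCBE1, the lincRNA LINC00707, the ubiquitin ligase MARCHF4, the growth factor carrier FGFBP1, the oxidase AOX1, the deiodinase DIO2, the activin subunit INHBB and PLCXD3 lay between −4.61 and −4.21. Each of these 23 genes passed edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p-values from 3.32e-28 (DIO2) to 4.10e-13 (RASAL1), apart from FOS, given above. The 12 called genes at 0 in both minus Dox libraries and the 4 at 0 in both plus Dox libraries were left out by the rule's minimum level.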

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

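Of 122 named genes, 104 kept their call and direction in each of the 15 other settings in which they were tested. Leaving out mitochondrially encoded genes moved nothing because those genes are listed at 0. Library size only gave 7865 higher and 2925 lower genes and 1898 past 2-fold higher, since it drops the factors that separate the groups; 8058 of the 10265 called genes were shared with the same sign and 67 with the opposite sign. Without any 1 library 4246 to 4952 genes were higher, 4318 to 5170 lower, 1008 to 1189 past 2-fold higher, 1010 to 1076 past 2-fold lower and 9 to 11 lists passed, where the lone library of a group is assumed to vary like the others. DESeq2 gave 3926 higher and 4132 lower genes, 8037 of the calls shared, and its list test was not run. The labels do not say whether replicate numbers pair the libraries. Deviations of libraries with the same number had a correlation of 0.07 over 6479 genes, which does not exclude a shared culture or day. A replicate block gave 5219 higher, 5195 lower, 1198 and 1083 past 2-fold and 10 lists, losing the cholesterol list (0.256), and changed no other call of a list or named gene. Of the lists, 11 passed camera, 0 with an estimated correlation, 21 in fry's mixed test, which has no other genes as reference, and 6 with the GC, length and abundance trend removed, a setting chosen after seeing the data. Log2 fold changes turned sign with the trend removed in ATF2 (−0.22), JUND (0.21), ATF7 (0.063), FOXA1 (0.025), KRT8 (0.28), PCNA (0.028) and CYC1 (0.011), and with library size only in BATF3 (0.077), JUND (0.15), ATF7 (0.21), MAFK (0.094) and FOXA1 (0.17). ATF7, at 0.00, also turned with the stricter filter (0.0032), after thinning (0.0055) and over single libraries left out (−0.034 to 0.012), and FOSB ranged there from −0.52 to 0.036. Lists that had not passed turned direction without passing, with these adjusted p-values. The AP-1 family turned in fry (0.930) and without minus Dox replicate 2, in a range of 0.603 to 0.955 over single libraries left out. MAPK genes turned with the block (0.883) and with each library left out (0.800 to 0.988). Fibroblast and endothelial markers turned with the stricter filter (0.716), with the block (0.883), in fry (0.105) and without either minus Dox library, in a range of 0.820 to 0.988 over single libraries left out. G2/M genes gave 0.573 and unfolded protein response genes 0.872 with library size only, and with the trend removed G2/M, ATF4 and hypoxia genes gave 0.601 each and unfolded protein response genes 0.132. The respiration list, which had passed, also turned with the trend removed (0.601). Apart from the settings that change the scale or the number of samples, the cause was not tested. In simulated data of this depth and group size, but with few changed genes, 40.8% of 1.2-fold changes were recovered among 17628 genes.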

Other observations

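Gene families grouped by symbol stem were examined after seeing the data. Of 183 families with at least 10 tested members, 3 were higher and 10 lower by camera with Benjamini-Hochberg adjustment, and 0 passed with an estimated correlation (adjusted p = 0.884). Large ribosomal subunit genes (RPL) fell in 45 of 48 members, with a median of −0.56 on the log2 scale, and small subunit genes (RPS) fell in 31 of 31, with a median of −0.53. These medians stayed below 0 with library size only (−0.35 and −0.31) and with the GC, length and abundance trend removed (−0.19 and −0.15). Annexins, which bind membranes under calcium, fell in 11 of 14 members (median −0.65, and −0.37 with SE 0.33 with the trend removed), and keratins in 10 of 15 with 3 higher (median −1.65, and −0.83 with SE 0.54 with the trend removed). RAB genes, the GTPases of vesicle traffic, rose in 37 of 65 members and fell in 9 (median 0.26, and 0.47 with library size only), and UBE genes of ubiquitin transfer rose in 23 of 38 and fell in 6 (median 0.23, and 0.45 with library size only).

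Several of the most abundant transcripts fell strongly, named here after their values were seen. The retinal dehydrogenase ALDH1A1 fell from 10304 to 4750 CPM, the keratin KRT81, whose close paralogs leave its count uncertain, from 4946 to 1455 CPM, and the transglutaminase TGM2 from 3009 to 1054 CPM. The semaphorin receptor NRP2 fell from 594 ± 17.6 to 66.8 ± 1.25 CPM and the TGF-beta pathway gene PMEPA1 from 1008 ± 25.7 to 128 ± 3.43 CPM (SD, n = 2). Called lincRNAs were higher in 105 and lower in 178 cases, against 4691 and 4452 for protein-coding genes, an odds ratio of 0.56 (two-sided Fisher's exact p = 2.93e-06, across genes, which are not independent).

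The weighing of FOS, of gene properties and scaling of AP-1 targets, and of marker RNA used tests chosen after seeing the data, though the bound for gene properties was written before its own result; the tests of depth, composition and genomic DNA were set before their results. FOS rose 4.34 further on the log2 scale than the next AP-1 family member, which is what reads of the integrated A-FOS gene counted to FOS would give. A rise of the FOS locus would give the same value, and no count per exon separates them. A general rise of immediate early genes was weighed with 10 others. Their median was −0.33 (scaled median absolute deviation 0.79), with 3 higher, 5 lower and EGR1 highest at 2.40, so these genes did not rise together. FOSB, JUNB, ATF3 and MAFF among them belong to the AP-1 family and DUSP1 to the AP-1 targets, which A-FOS may itself move. Whether the FOS locus rose alone or with some of them is therefore not decided. Counted transgene reads may explain the rise, as a hypothesis that reads over exons could test.

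The fall of AP-1 targets was set against bias and scaling. After removal of the GC, length and abundance trend, which holds 9.46% of the variance of fold changes, the list's median was −0.82 (SE 0.25), and with library size only it was −0.77 (SE 0.22) while the median of all genes was 0.22. The value with the trend removed argues against these trends as the whole cause. Library size only moves all genes by nearly the same amount, so the list's distance from the other genes could not change. That value shows only that the list's median stays negative without the TMM factors. As a hypothesis that no test here decides, a loss of AP-1 activity under A-FOS may account for the fall; an effect of doxycycline itself stays open too, and the list's call is lost with an estimated correlation.

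More genes had a count in plus Dox although these libraries had the lower totals, so a difference in depth would work against it. Thinning to the smallest total therefore had an outcome largely fixed beforehand, a gap of 833 genes between the closest libraries. Thinning to the smallest TMM-scaled depth left a gap of 459 genes, which argues against a few abundant genes as the whole cause. Each gap is the lowest plus Dox value minus the highest minus Dox value over all 20 thinnings. Leukocyte RNA was considered because CD79B, SPN, IL10RA and TBX21 held at least 4.57 unscaled CPM in each plus Dox library. These 4 genes were picked after their values were seen. The 15 leukocyte markers together had 6.93 and 8.12 CPM in minus Dox and 6.91 and 6.94 in plus Dox. They rose by at most 0.017 between any 2 libraries of the groups, with a range of 1.19 within a group. This argues against leukocyte RNA as the source of the counts of those 4 genes. A trace too small to move the markers' sum could still give single counts in more genes, so the gap itself is not decided. For fibroblasts or endothelial cells the markers' median of −0.19 with members going both ways decides nothing, and the list's unscaled CPM (66.7 and 73.5 against 90.6 and 94.0) have a ratio of 0.991 without THY1. Genomic DNA cannot be told apart: olfactory receptor genes had a ratio of 1.40 (95% interval 1.11 to 1.76) and 0.952 to 1.52 after TMM scaling, both for counting error only. A wider set of transcribed genes under doxycycline may also give the gap, and was not tested.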
